A study of Mus musculus with 66 samples.

How the data were processed

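The values are the deposited RPM (reads per 1e+06 reads of a library), which the authors made from poly(A)-selected, directional libraries amplified with 12 PCR cycles. The labels name TopHat2, Bowtie2 2.0.13, featureCounts 1.5.1 and R 3.4.4 with the mouse build mm10. Their roles, order and settings, the annotation, the strand setting of the counting and any filter are not given. The table holds 24062 genes in 66 libraries, and each library sums to 1e+06. Within a library all values were whole multiples of one smallest step, so whole reads were recovered for all entries to within 0.01 of a read. The RPM are therefore not divided by transcript length.

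The comparisons, the gene lists, the filter, the main test and most of the alternative settings were fixed before the data were examined. Genes were kept in a fit when the mean reached 1 RPM in at least 1 of its groups. The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(RPM + 1) with one mean per group, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Separate fits were made. The in vivo fit held 27 libraries with 18 residual degrees of freedom, and so did the in vitro course from D5 to D20. Comparisons of D20 with ovarian oocytes used a joint fit of these 54 libraries with 36 degrees of freedom. The 12 D21 libraries were fitted alone with 6 degrees of freedom. Counts of genes with a log2 change of at least 1 apply no further test. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

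The gene lists were tested with camera of limma, two-sided, at a preset inter-gene correlation of 0.01, for lists with at least 5 measured members and adjusted over the lists of a comparison. Each call was repeated with an estimated correlation, and 2 of 134 held, the oocyte growth list at P6 and at P4. A list adjusted p is therefore given with its value for an estimated correlation. Camera compares a list with all other genes, so its sign can differ from that of the list's median. The lists covered oocyte growth and maternal genes, follicle-formation transcription factors, meiotic prophase, primordial germ cell and pluripotency genes, proliferation, DNA methylation, transposon defence, the PI3K/FOXO pathway, FOXO targets, HIF targets, glycolysis, nuclear-encoded respiratory chain (OXPHOS), cholesterol biosynthesis, cytosolic ribosome, ribosome biogenesis, unfolded protein and integrated stress response, p53 targets and autophagy. Markers of granulosa cells, stroma and theca, endothelium, and blood and immune cells stood for other cells of the ovary. A list of mitochondrially encoded genes had 0 members in the table. The small-oocyte and large-oocyte lists were the genes called at both P4 and P6 with a log2 change of at least 1, taken from libraries that enter no D21 comparison. Other lists rest on general knowledge of the genes.

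Genes are named by a fixed rule, with Foxo3 always given. From each comparison came the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap and whose higher mean was at least 20 RPM, with predicted genes passed over. Each described list gave up to 3 called members with the largest change, or up to 2 highly expressed members where none was called. Some genes that meet this rule are not reported here. A panel of 22 genes of oocyte growth, meiosis and oxygen response was added. The lists described are those that passed, the HIF and FOXO targets, the oocyte growth list and the markers of other cells.

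A count of 3 reads corresponded to 0.129 to 0.619 RPM, depending on the library. Floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The p-values measure the spread between libraries only. Between replicate libraries the chi-square per gene was 3.57 to 243, where sampling of reads alone gives 1, and Pearson's r was 0.921 to 0.996.

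RPM express shares of a library, so a broad shift moves all genes. The median log2 change of all genes was 0.41 at P6 and 0.34 at P4 (small against large), 0.14 for E18.5 against E14.5, -0.07 for P3 against E18.5, 0.17 for D11 against D5, -0.66 for D20 against D11, -0.27 for D20 against P6 small and 0.05 for D20 against P6 large. In the D21 fit it lay between -0.12 and 0.21. Splits into higher and lower genes after rescaling by median-of-ratios size factors are given beside the main ones.

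Reads were simulated gene by gene, with changes placed in genes of at least 5 RPM. With the spread of all in vivo libraries, limma called 55.2% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes in the P6 comparison. False calls numbered 7 among 14122 genes. With the spread of the WT hypoxia comparison it called 4.48%, 43.3% and 100%, with 7 false calls among 13796 genes.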

Results

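RNA of mouse female germ cells and oocytes was sequenced along development in the ovary, along development from embryonic stem cells in culture, and after 21 days of culture with or without low oxygen and a Foxo3 transgene. The 66 libraries formed 24 groups. In vivo cells came from ovaries with a stella-ECFP reporter, with 3 libraries at each of E14.5, E16.5, E18.5, P1 and P3 and 3 each of small and large oocytes at P4 and P6. They are labelled germ cells up to E18.5 and D11 and oocytes afterwards. The culture course used reconstituted ovaries, which are aggregates of germ cell-like cells made from embryonic stem cells with gonadal somatic cells of E12.5 embryos, with 3 libraries at each of D5, D7, D9, D10, D11, D13, D15, D17 and D20. The D21 set held 2 libraries in each of 6 groups, wild type (WT) or carrying the Foxo3dNES transgene (Tg), in normoxia, in hypoxia (5% O2), or with the oxygen not given. In units of 1e+06 reads (M), depth was 13.9 to 23.2 M in vivo, 14.7 to 22.8 M in the course and 4.84 to 21.3 M at D21. The 4 libraries of no given oxygen held only 4.84 to 8.72 M.

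**Figure D1:**
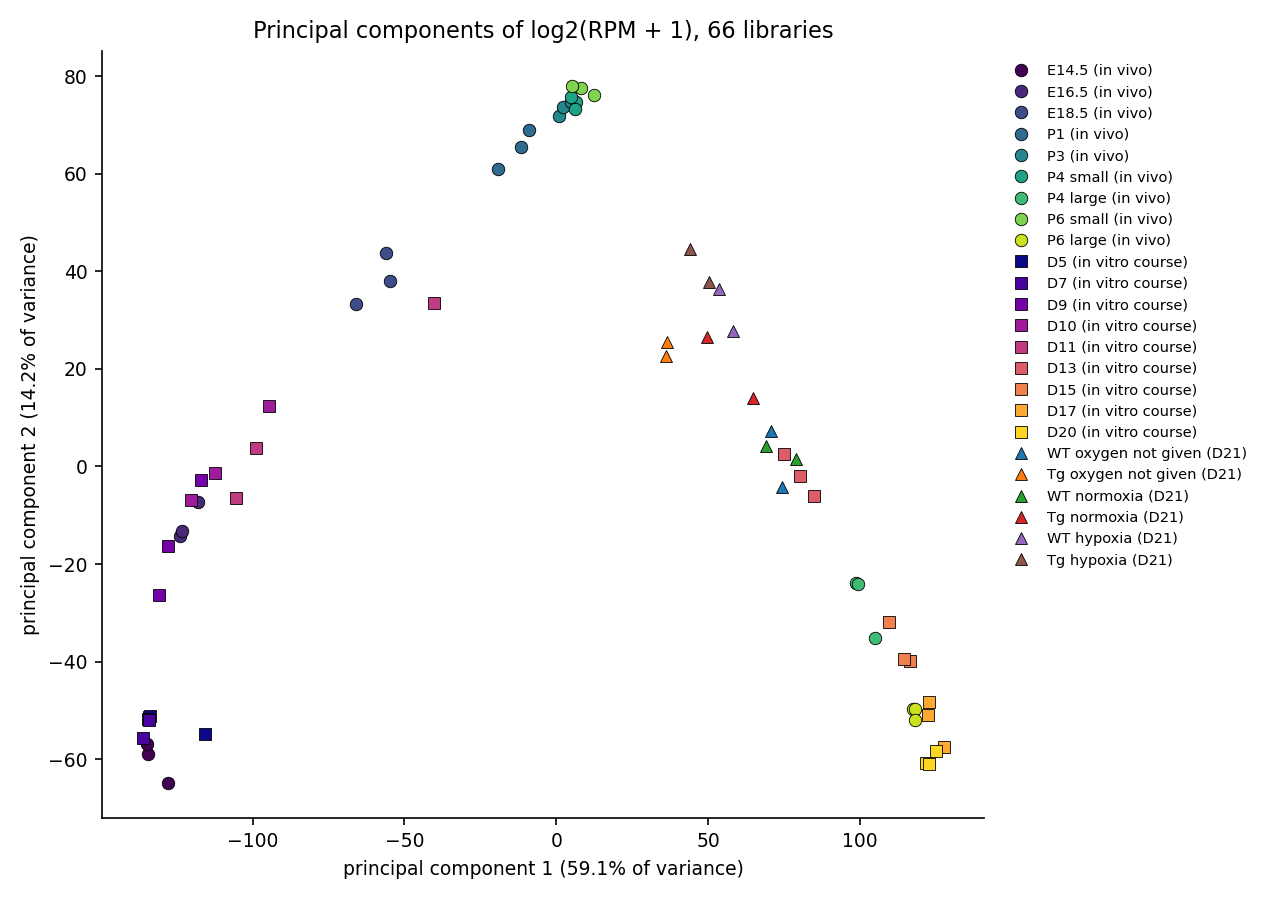
Principal components of log2(RPM + 1) over 13834 genes, with component 1 (59.1% of variance) on the horizontal and component 2 (14.2%) on the vertical axis. Each dot is a library, coloured by group, and large oocytes and late culture lie apart from small oocytes and germ cells.

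Small and large oocytes were compared at P6 to show which genes separate oocytes held small from those that have begun to grow. Large oocytes carried the RNAs of the oocyte-secreted growth factors and of the egg coat. Gdf9, whose protein drives follicle growth, was 293 ± 28.4 RPM (SD, n = 3) in small and 4920 ± 218 RPM in large oocytes, a log2 change of -4.07 with adjusted p = 2.7e-16 by limma. Its partner Bmp15 was 15.9 ± 1.88 against 597 ± 44.6 RPM, and the zona pellucida genes Zp2 and Zp3 were lower in small oocytes by log2 changes of -1.46 and -2.43. Small oocytes held more RNA of Sohlh1, a transcription factor of primordial follicles, at 594 ± 11.1 against 88 ± 8.59 RPM, and of Sycp3, a protein of the meiotic chromosome axis, at 463 ± 59.9 against 58.5 ± 4.64 RPM. Foxo3, a transcription factor that holds primordial follicles quiescent, was 195 ± 5.3 RPM in small and 90.9 ± 4.68 RPM in large oocytes, with no overlap between the groups.

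Of 15401 genes tested at P6, 11300 were called, 7904 higher and 3396 lower in small oocytes, and 6307 of them had a log2 change of at least 1. After rescaling the split was 5275 higher and 5574 lower. edgeR gave 5695 and 5218, and DESeq2 5462 and 5534. Foxo3 had a log2 change of 1.09 (adjusted p = 3.9e-09), and edgeR gave 0.56 with adjusted p = 8.5e-05. Among the largest differences toward small oocytes were those in Adam19, a membrane metalloprotease (log2 change 8.14), the cholesterol exporter Abca1 (6.21), the selenium carrier Sepp1 (6.05), Pgm5 (6.03) and the kinase Aatk (5.89). The largest toward large oocytes were in Nlrp9b (-8.01), the oocyte poly(A)-binding protein gene Pabpc1l (-7.95), the F-box genes Fbxw16 (-7.70), Fbxw28 (-7.68) and Fbxw14 (-7.54), and the homeobox gene Obox5 (-7.55).

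Among 36 oocyte growth and maternal genes, 34 were lower and 0 higher in small oocytes, with a median log2 change of -3.65 (adjusted p = 3.9e-21, or 0.029 with an estimated correlation). Nlrp2 (-7.35) and Oosp1 (-6.63) were among them. All 80 cytosolic ribosome genes were higher in small oocytes, such as Rps27 at 571 ± 24.1 against 84.9 ± 4.17 RPM (n = 3), with a median of 1.94 (adjusted p = 2.1e-17, or 0.59 with an estimated correlation). Of 76 respiratory chain genes 71 were higher and 1 lower, or 71 and 2 adjusted over the list alone, with a list median of 1 (adjusted p = 2e-06, or 0.67 with an estimated correlation). Of 19 p53 targets 17 were higher and 1 lower, including the cell cycle inhibitor Cdkn1a at 58.9 ± 15.9 against 2.66 RPM, Bbc3 (3.90) and Btg2 (3.37), with a median of 1.81 (adjusted p = 0.0079, or 0.26 with an estimated correlation). Among 12 DNA methylation genes 7 were lower, such as Dnmt1 at 260 ± 2.57 against 4750 ± 64 RPM and Dnmt3l (-5.45), and 3 were higher, with a median of -0.77 (adjusted p = 0.0094). Proliferation genes had 8 higher and 15 lower of 30 and a median of -0.09 (adjusted p = 0.028), both lists being at 0.59 with an estimated correlation.

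Of 26 FOXO targets at P6, 19 were higher and 2 lower in small oocytes, or 20 and 2 when adjusted over the list alone. They included the insulin receptor gene Insr at 77 ± 9.4 against 5.36 RPM, Cat (2.73) and Pink1 (2.24). The list median was 1.41 with a adjusted p of 0.052, so the list as a whole did not pass. Of 41 HIF targets 19 were higher and 9 lower (median 0.22, adjusted p = 0.89), with Ldha higher (2.98) and Car9 (-6), Bhlhe40 (-5.23) and Ddit4 (-4.92) lower in small oocytes. The remaining lists did not pass. Their medians were 0.84 for the PI3K/FOXO pathway with 17 of 24 genes higher, 1.03 for meiotic prophase with 29 of 40 higher, 0.83 for autophagy, 0.70 for cholesterol biosynthesis, 0.49 for ribosome biogenesis, 0.40 for follicle-formation factors and 0.34 for the unfolded protein and stress response. The median was 0.03 for primordial germ cell genes, 0.14 for glycolysis and 0.57 for transposon defence, all with a test sign of down. Granulosa markers had 7 higher and 6 lower of 22, or 6 and 6 adjusted over the list alone (median 0.37, test sign down, adjusted p = 0.19). Stroma/theca markers had 9 higher and 1 lower of 13 (median 0.76, adjusted p = 0.65). Endothelial markers had 1 higher and 3 lower of 7 (-0.44, adjusted p = 0.23). Blood/immune markers had 0 higher and 3 lower of 11 (0.33, test sign down, adjusted p = 0.39).

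Oocytes of P4 were compared in the same way to show whether the same genes part small from large oocytes 2 days earlier. Gdf9 was 340 RPM in small and 3900 ± 257 RPM in large oocytes (n = 3 each; log2 change -3.52), and Bmp15 (-3.99), Zp2 (-2.00) and Zp3 (-2.87) were lower in small oocytes as well. Eif4e1b, an oocyte cap-binding protein gene, was 12.6 against 1530 ± 117 RPM, a log2 change of -6.85. Foxo3 was 188 ± 23.3 against 95 ± 6.25 RPM with a log2 change of 0.97 (adjusted p = 4.2e-08), and 0.57 in edgeR (adjusted p = 9e-05). Sohlh1 was higher in small oocytes (1.53), and Figla, a regulator of zona genes, had a log2 change of 0.47 (adjusted p = 0.049), or -0.01 after rescaling.

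At P4 10663 genes were called, 7507 higher and 3156 lower in small oocytes, with 4893 at a log2 change of at least 1. The split after rescaling was 4779 and 5116, edgeR gave 5145 and 4707, and DESeq2 4928 and 5012. Adam19 (6.73), Slc38a1 (5.19), Pgm5, Igdcc4 and Aatk were among the leading genes toward small oocytes, and Pabpc1l (-7.70), Nlrp9b (-6.88), Eif4e1b, Fbxw14, Fbxw28 and Fbxw16 toward large. The oocyte growth list had 0 higher and 33 lower, or 1 and 33 adjusted over the list alone, with a median of -3.14 (adjusted p = 6e-23, or 0.02 with an estimated correlation). All 80 ribosome genes were higher (median 1.46, adjusted p = 4.4e-17, or 0.55 with an estimated correlation). Respiratory chain genes had 63 higher and 1 lower, or 65 and 1 adjusted over the list alone (0.67, adjusted p = 0.00033, or 0.81 with an estimated correlation). FOXO targets had 20 higher and 1 lower of 26 (1.24, adjusted p = 0.013, or 0.49 with an estimated correlation). The p53 targets had 17 higher and 1 lower (1.24, adjusted p = 0.013, or 0.4 with an estimated correlation). Ribosome biogenesis genes had 31 higher and 4 lower (0.48, adjusted p = 0.029) and DNA methylation genes 3 higher and 7 lower (-0.79, adjusted p = 0.0038), each at 0.55 with an estimated correlation.

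HIF targets at P4 had 22 higher and 7 lower (median 0.65, adjusted p = 0.6). Granulosa markers had 11 higher and 5 lower (0.48, test sign down, adjusted p = 0.71). Counts for stroma/theca markers were 9 higher and 1 lower (0.85, adjusted p = 0.68). Endothelial markers had 1 higher and 3 lower (-0.06, adjusted p = 0.3). Counts for blood/immune markers were 0 higher and 3 lower (0.27, test sign down, adjusted p = 0.34). Between the ages, which share no libraries, 6935 genes were higher in small oocytes at both where 3850 were expected from the separate counts, 2871 were lower at both where 696 were expected, and 16 were called in opposite directions. Pearson's r of the log2 changes was 0.96 across genes (not independent replicates).

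Germ cells of E18.5 were compared with those of E14.5 to follow the passage from meiotic entry to follicle assembly. Stra8, the switch into meiosis, fell by a log2 change of 8.61 from 582 ± 71.7 to 0.481 RPM (n = 3), and Rec8, the meiotic cohesin, fell by 6.24. Of the factors of follicle assembly, Nobox rose from 1.33 to 478 ± 11.2 RPM (7.73), with Sohlh1 (7.54), Lhx8 (6.34) and Figla (3.32). Nlrp5, a maternal-effect gene, rose to 898 ± 120 RPM (8.69), and Kit, the receptor for a follicle-cell ligand, from 133 to 1560 RPM (3.57). Foxo3 rose from 47.4 ± 4.46 to 296 ± 25.7 RPM, a log2 change of 2.62 with adjusted p = 3.7e-16.

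In this step 10782 genes were called, 6157 up and 4625 down, with 5420 at a log2 change of at least 1. Rescaling gave 5182 up and 5468 down, edgeR 5457 and 5140, and DESeq2 5312 and 5348. The largest rises besides these were in Ccno (7.54), the muscle protein gene Neb (7.52) and Nlrp4f (7.44). The largest falls besides Stra8 and Rec8 were in Tppp (-5.62), the glycine cleavage gene Gldc (-5.56), the pluripotency gene Utf1 (-5.48) and the cyclin Ccnd1 (-5.43). Of the oocyte growth genes 30 rose and 0 fell, among them Zp2 (6.50), Dppa3 (3.54) and Gdf9 (4.32), with a median of 3.13 (adjusted p = 4.6e-09), and meiotic prophase genes had 5 up and 28 down of 40 (-0.99, adjusted p = 4.4e-06), each at 0.19 with an estimated correlation, while Sycp3 stood at a log2 change of 0.15 (adjusted p = 0.4). Primordial germ cell genes had 2 up and 16 down of 19, such as Sox2 (-5.34), Tfap2c (-3.86) and Pou5f1 (-2.09), with a median of -2.81 (adjusted p = 4.4e-06, or 0.19 with an estimated correlation). Proliferation genes had 5 up and 23 down, such as Top2a (-3.79) and Mki67 (-1.93), with a median of -0.78 (adjusted p = 3.9e-05, or 0.2 with an estimated correlation). Ribosome genes had 2 up and 63 down, or 2 and 64 adjusted over the list alone (-0.64, adjusted p = 1.5e-09, or 0.62 with an estimated correlation). Follicle-formation factors had 10 up and 4 down of 14 (2.63, adjusted p = 0.028, or 0.55 with an estimated correlation). Autophagy genes had 17 up and 2 down of 25 (0.42, adjusted p = 0.036, or 0.2 with an estimated correlation). Glycolysis genes had 5 up and 12 down of 20 (-0.76, adjusted p = 0.046, or 0.62 with an estimated correlation).

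FOXO targets between E14.5 and E18.5 had 9 up and 9 down (median -0.02, adjusted p = 0.54) and HIF targets 12 up and 17 down (-0.06, adjusted p = 0.47), with Pdk1 (3.05) and Ak4 (3.19) up and the glucose transporter Slc2a3 (-4.25) down. Granulosa markers had 12 up and 2 down (1.09, adjusted p = 0.31). Stroma/theca markers had 8 up and 1 down (1.62, adjusted p = 0.22). Endothelial markers had 3 up and 2 down (0.42, test sign down, adjusted p = 0.91) and blood/immune markers 6 and 3 (0.81, adjusted p = 0.92).

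From E18.5 to P3, when primordial follicles form, RNAs of the maternal store rose and those of late meiosis fell. Nlrp14, a maternal NLR gene, rose from 61.1 to 1490 RPM (log2 change 4.64), Zp3 rose by 4.63, Zp2 by 3.19 and Gdf9 by 3.03. Taf7l, a germline TAF7 paralogue, fell by 6.43 from 697 ± 163 to 7 RPM (n = 3), and the synaptonemal gene Syce3 (-3.85) and the recombination gene Spata22 (-4.28) fell with it. Foxo3 fell by 0.63 to 191 ± 14.7 RPM (adjusted p = 5.1e-05). Cdkn1b, an inhibitor of the cell cycle, rose by 1.73, and Vegfa fell by 2.26.

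Here 8974 genes were called, 3997 up and 4977 down, and 2913 had a log2 change of at least 1. Rescaling gave 4242 and 4526, and edgeR 4401 and 4169. Khdc1a (5.80), Adam19 (5.19), Oas1c (5.04), Khdc1b and Oas1d (4.72) rose most with Nlrp14, and Tex101 (-6.27), the imprinted RNA H19 (-5.28), Nxf2, Trank1 and Tex16 fell most with Taf7l. The oocyte growth list had 31 up and 1 down (median 2.07, adjusted p = 3.8e-15) and meiotic prophase 1 up and 33 down (-1.10, adjusted p = 2e-10), each at 0.054 with an estimated correlation. Transposon defence genes had 2 up and 16 down of 20, with Tdrd9 at -1.67 (-0.79, adjusted p = 0.0017, or 0.37 with an estimated correlation). Ribosome genes had 33 up and 6 down (0.21, adjusted p = 0.0019, or 0.71 with an estimated correlation). Ribosome biogenesis had 4 up and 21 down (-0.30, adjusted p = 0.016) and FOXO targets 15 up and 8 down (0.60, adjusted p = 0.026), each at 0.48 with an estimated correlation. Cholesterol biosynthesis had 10 up and 2 down (0.30, adjusted p = 0.025, or 0.51 with an estimated correlation). HIF targets had 16 up and 13 down, or 17 and 13 adjusted over the list alone (0.16, adjusted p = 0.28). Granulosa markers had 1 up and 14 down (-0.81, adjusted p = 0.025, or 0.51 with an estimated correlation). Counts for stroma/theca markers were 0 up and 7 down (-0.78, adjusted p = 0.29). Endothelial markers had 1 up and 3 down (-0.74, adjusted p = 0.31). Blood/immune markers had 0 up and 4 down (-0.74, adjusted p = 0.39).

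In culture, D11 was compared with D5 to show whether the same passage takes place in reconstituted ovaries. Padi6, a maternal-effect gene, rose by a log2 change of 8.51, from 3.34 to 1980 ± 1700 RPM (n = 3), and Nobox by 7.40, from 0.5 to 306 ± 248 RPM. Zp2 (7.80), Zp3 (7.11), Nlrp5 (7.08), Sohlh1 (5.81) and Gdf9 (5.70) rose as well, and Stra8 fell by 1.92 to 262 ± 190 RPM. Foxo3 rose from 44.5 ± 29 to 107 ± 37.6 RPM, with a log2 change of 1.48 (adjusted p = 0.001). Markers of granulosa cells rose in the same libraries, with Amhr2, the receptor for anti-Müllerian hormone, going from 4.48 to 93.9 ± 22.8 RPM.

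Of 16065 genes, 7432 were called, 5019 up and 2413 down, with 3602 at a log2 change of at least 1, and rescaling gave 4211 up and 3270 down. Without D11 replicate 3 the count was 6424, and without D11 replicate 1 it was 7808. Gpnmb (6.90) was the only other gene among the 6 largest rises, and Phlda2 (-4.01), Gata2 (-3.76), Rec8 (-3.23), BC048679, Fgfr3 (-2.98) and Notum (-2.97) fell most. The oocyte growth list had 31 up and 0 down, or 33 up adjusted over the list alone (median 3.53, adjusted p = 3.5e-17) and follicle-formation factors 9 up and 1 down, or 9 and 4 adjusted over the list alone (1.65, adjusted p = 0.0076), each at 0.33 with an estimated correlation. Primordial germ cell genes had 2 up and 13 down, or 2 and 14 adjusted over the list alone (-1.07, adjusted p = 3.3e-05), meiotic prophase 4 up and 13 down (-0.33, adjusted p = 0.00088) and proliferation 5 up and 12 down, or 5 and 13 adjusted over the list alone (-0.31, adjusted p = 0.0015), each at 0.33 with an estimated correlation. Ribosome genes had 0 up and 76 down, or 78 down adjusted over the list alone (-0.96, adjusted p = 2e-27, or 0.33 with an estimated correlation). Respiratory chain genes had 1 up and 24 down, or 1 and 22 adjusted over the list alone (-0.30, adjusted p = 1.3e-06, or 0.51 with an estimated correlation). FOXO targets had 13 up and 2 down, or 14 and 2 adjusted over the list alone (0.75, adjusted p = 0.015, or 0.33 with an estimated correlation). DNA methylation genes had 7 up (0.88, adjusted p = 0.035, or 0.34 with an estimated correlation). The p53 targets had 9 up and 0 down (0.72, adjusted p = 0.024), cholesterol biosynthesis 2 and 6 (-0.26, adjusted p = 0.013) and ribosome biogenesis 5 and 6, or 4 and 3 adjusted over the list alone (-0.18, adjusted p = 0.029), each at 0.33 with an estimated correlation. HIF targets had 16 up and 6 down of 43 (0.36, adjusted p = 0.31).

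Among the markers of other cells at D11, 16 of 24 granulosa genes rose, or 18 adjusted over the list alone, including Kitl (4.99) and Wt1 (4.22), with a median of 2.03 (adjusted p = 1.3e-06, or 0.33 with an estimated correlation). Of 16 stroma/theca genes 15 rose, such as Col3a1 (5.43), with a median of 2.73 (adjusted p = 1.9e-05), and 10 of 11 blood/immune genes, such as Lyz2 (5.01), with a median of 3.17 (adjusted p = 1.8e-05), each at 0.33 with an estimated correlation. Endothelial markers had 5 up and 2 down of 10 (0.70, adjusted p = 0.68). The in vivo and the cultured step shared 3229 genes up where 1850 were expected and 1635 down where 705 were expected, and 475 genes were called in opposite directions. Pearson's r was 0.66 and Spearman's rho 0.61 across genes (not independent replicates).

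D20 was compared with D11 to follow oocyte growth in culture. Gdf9 rose from 124 ± 119 to 5370 ± 158 RPM (n = 3; log2 change 5.86), Bmp15 rose by 7.22, Zp3 by 4.70 and Zp2 by 4.07. Nlrp9b rose from 2.51 to 853 ± 24.7 RPM (8.12). The meiotic genes Stra8 (-7.51) and Sycp3 (-3.22) fell, as did Ldha (-4.91). Thbs1 fell from 402 ± 219 to 0.139, Xist from 292 ± 124 to 0.182 RPM and Col3a1 by 7.56. Most markers of other cells fell too, so falls need not lie in oocytes. Foxo3 changed by -0.35 (adjusted p = 0.35).

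There were 12465 calls, 3621 up and 8844 down, of which 8737 had a log2 change of at least 1, and rescaling gave 5528 up and 6475 down. Oog3 (9.07), C87977 (8.61), Nlrp2 (8.01), Cpa1 (8) and Obox2 rose most with Nlrp9b, and Taf7l (-8.04), Cyr61 (-7.88), Xist (-7.88) and Jun (-7.62) fell most with Thbs1. All 36 oocyte growth genes rose (median 4.91, adjusted p = 5.4e-24, or 0.42 with an estimated correlation). All 80 ribosome genes fell (-2.18, adjusted p = 6.1e-12, or 0.74 with an estimated correlation), as did all 19 p53 targets (-2.19, adjusted p = 0.0011, or 0.54 with an estimated correlation). Meiotic prophase genes had 3 up and 34 down (-3.19, adjusted p = 2e-05, or 0.73 with an estimated correlation). FOXO targets had 2 up and 21 down (-1.93) and cholesterol biosynthesis 2 up and 20 down (-1.74), each with adjusted p = 0.014, or 0.74 with an estimated correlation. Respiratory chain genes had 1 up and 60 down, or 1 and 61 adjusted over the list alone (-0.85, adjusted p = 0.0075, or 0.81 with an estimated correlation). Stroma/theca markers had 0 up and 15 down (-3.27, adjusted p = 0.016, or 0.76 with an estimated correlation). Granulosa markers had 5 up and 16 down (-2.14, adjusted p = 0.18). Blood/immune markers had 0 up and 10 down (-3.25, adjusted p = 0.077). Endothelial markers had 2 up and 5 down (-0.59, test sign up, adjusted p = 0.93). HIF targets had 11 up and 23 down (-0.52, adjusted p = 0.73).

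Cultured oocytes of D20 were set against P6 oocytes to show how far they match ovarian oocytes. Against P6 large oocytes the growth factor and zona RNAs were close, with Gdf9 at 5370 ± 158 against 4920 ± 218 RPM (n = 3; log2 change 0.13, adjusted p = 0.94) and Zp3 at 7370 against 6980 RPM. Foxo3 was 81 ± 11.1 against 90.9 ± 4.68 RPM (-0.17, adjusted p = 0.82). The kinase gene Stk32a was higher in culture, at 56.6 ± 1.75 against 0.0973 RPM, and Slc26a5 lower, at 1.07 against 59.4 ± 24.3 RPM. Rictor, a subunit of the mTORC2 kinase complex, was lower in culture (-0.67).

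Of 16452 genes 2337 differed, 1582 higher and 755 lower in D20, with 627 at a log2 change of at least 1, and the split was 1430 and 1235 after rescaling, 888 and 1030 with edgeR and 1142 and 1166 with DESeq2. The count fell to 1422 without P6 large replicate 1 and to 1474 without D20 replicate 2. Spesp1 (4.42), Pla2g4e (3.67), Steap4 (3.37), Agpat9 (3.36) and Manba (3.32) were next to Stk32a, and AK129341 (-3.17), Armcx3 (-2.78), Acsf2 (-2.11) and Slc17a5 (-1.50) were among those next to Slc26a5. The PI3K/FOXO pathway had 1 higher and 4 lower, or 1 and 6 adjusted over the list alone (median -0.18, adjusted p = 0.0013) and the ribosome list 0 higher and 1 lower, or 0 and 0 adjusted over the list alone (-0.17, adjusted p = 1.1e-05), each at 0.99 with an estimated correlation. Of the oocyte growth genes 3 were higher, with Oog1 at 1.65 (0.13, adjusted p = 0.54). HIF targets had 5 higher, or 6 and 1 lower adjusted over the list alone, with Stc2 at 2.29 (0.16, adjusted p = 0.54). FOXO targets had 2 higher and 1 lower, or 0 and 0 adjusted over the list alone (0.08, test sign down, adjusted p = 0.98). Granulosa markers had 3 higher, or 5 adjusted over the list alone, with Gata4 at 1.57 (0.11, adjusted p = 0.54). Counts for stroma/theca markers were 0 called (adjusted p = 0.71). Endothelial markers had 1 higher, or 0 adjusted over the list alone (0.05, adjusted p = 0.95). Counts for blood/immune markers were 2 higher, with C1qb at 1.63 (adjusted p = 0.95).

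Against P6 small oocytes, 11004 genes differed from D20, 3857 higher and 7147 lower, and rescaling gave 5578 and 4959. Nlrp9b (9.05), Fbxw16 (8.23), Pabpc1l (8.21), Obox5 (8.11), Fbxw19 and Fbxw28 were most above, and Adam19 (-8.23), Sepp1 (-6.41), Abca1 (-6.30), Slc38a1 (-6.16) and Aatk among those most below. Gdf9 (4.20) and Bmp15 (5.56) were higher in D20, and Foxo3 was lower (-1.26, adjusted p = 5e-05). Oocyte growth genes had 33 higher and 1 lower (median 4.08, adjusted p = 7.5e-18, or 0.36 with an estimated correlation). Ribosome genes had 0 higher and 80 lower (-2.11, adjusted p = 1.5e-19) and respiratory chain genes 2 and 67, or 2 and 69 adjusted over the list alone (-0.97, adjusted p = 3.1e-06), each at 0.66 with an estimated correlation. The p53 targets had 0 higher and 17 lower (-1.94, adjusted p = 0.0017, or 0.36 with an estimated correlation) and FOXO targets 3 and 18 (-1.34, adjusted p = 0.04, or 0.66 with an estimated correlation). DNA methylation genes had 7 higher and 3 lower (1.16, adjusted p = 0.031) and proliferation genes 14 and 4 (0.23, adjusted p = 0.038), each at 0.66 with an estimated correlation. HIF targets had 10 higher and 20 lower (-0.29, adjusted p = 0.94). Granulosa markers had 7 higher and 7 lower (-0.29, test sign up, adjusted p = 0.17). Stroma/theca markers had 1 higher and 6 lower, or 1 and 5 adjusted over the list alone (-0.64, adjusted p = 0.9). Endothelial markers had 3 higher and 1 lower (0.21, adjusted p = 0.28). Blood/immune markers had 3 higher and 2 lower, or 2 and 0 adjusted over the list alone (-0.22, test sign up, adjusted p = 0.51).

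Each cultured group was ranked by its Spearman correlation with the in vivo groups over 16540 genes, which are not independent replicates. D5 and D7 were closest to E14.5, at 0.976 and 0.979, and D11 to E18.5, at 0.93 with P1 next at 0.922. D13 was closest to P4 large oocytes at 0.97, and D20 to P6 large oocytes at 0.986. At D21, WT normoxia was closest to P4 large oocytes at 0.942 and Tg normoxia to the same group at 0.95. WT hypoxia was closest to P6 small oocytes at 0.96, with P4 small next at 0.958, and Tg hypoxia to P6 small at 0.967. By the 2000 most variable genes WT hypoxia was instead closest to P4 large oocytes, at 0.847.

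**Figure D2:**
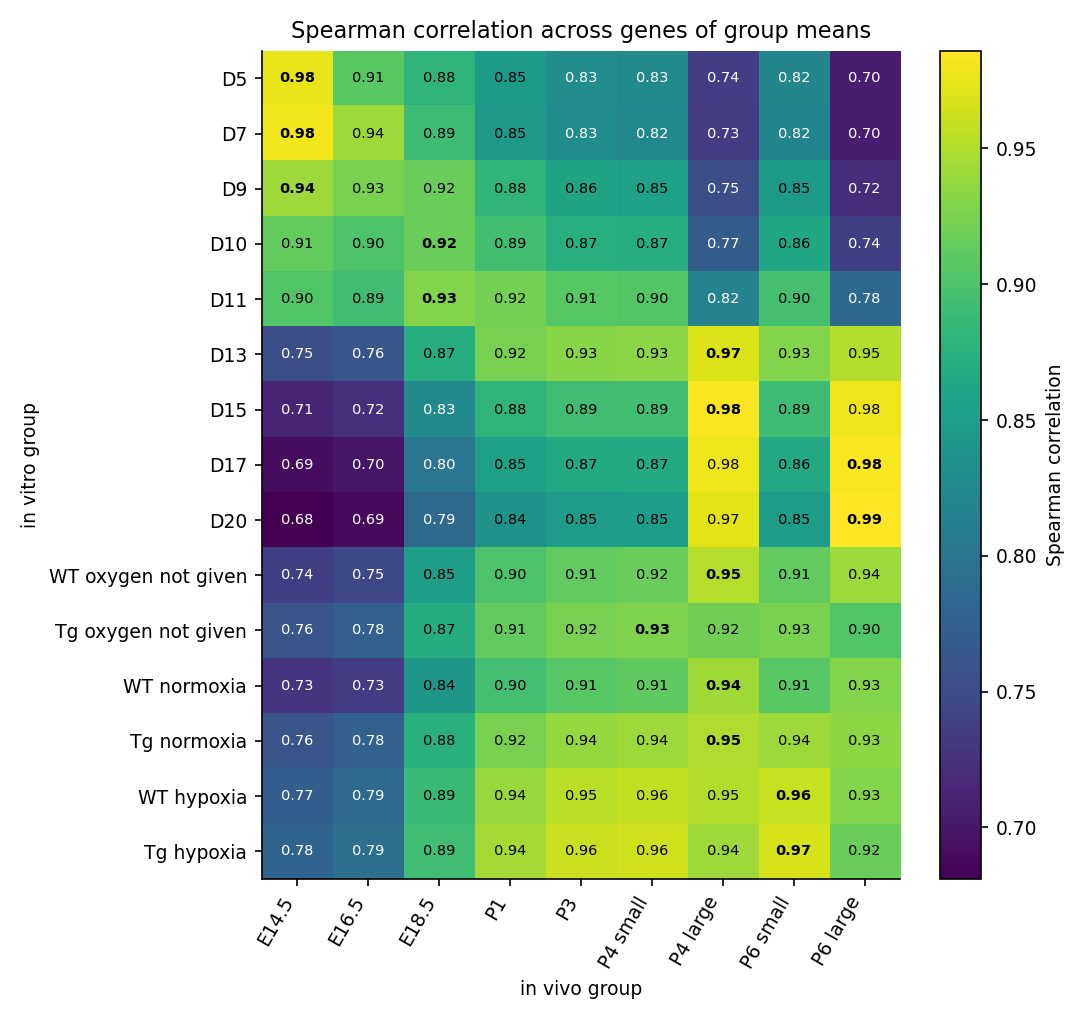
Spearman correlation of the mean log2(RPM + 1) of each cultured group (vertical axis) with each in vivo group (horizontal axis) over 16540 genes, as a colour scale without units. D20 peaks at P6 large oocytes (0.986) and both hypoxia groups at P6 small oocytes (0.96 and 0.967).

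Foxo3, at chromosome 10 from 42181841 to 42276755 on the minus strand (mm10; ENSMUSG00000048756.11), rose and then fell both in the ovary and in culture. In vivo it peaked at E18.5 with 296 ± 25.7 RPM (n = 3) and stood at 220 ± 3.2 RPM at P1. In the culture course from D5 to D20 the highest group mean was 107 RPM, at D10 and D11, while D13 to D20 lay between 56.6 and 81 RPM. At D21 it was 66.6 ± 30.9 RPM in WT normoxia and 126 ± 3.46 RPM in WT hypoxia (n = 2 each). Tg libraries held 293 ± 36.1 RPM with the oxygen not given, 323 ± 1.32 RPM in normoxia and 366 ± 2.26 RPM in hypoxia. Reads of the transgene and of the endogenous gene are not separated in the table.

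**Figure D3:**
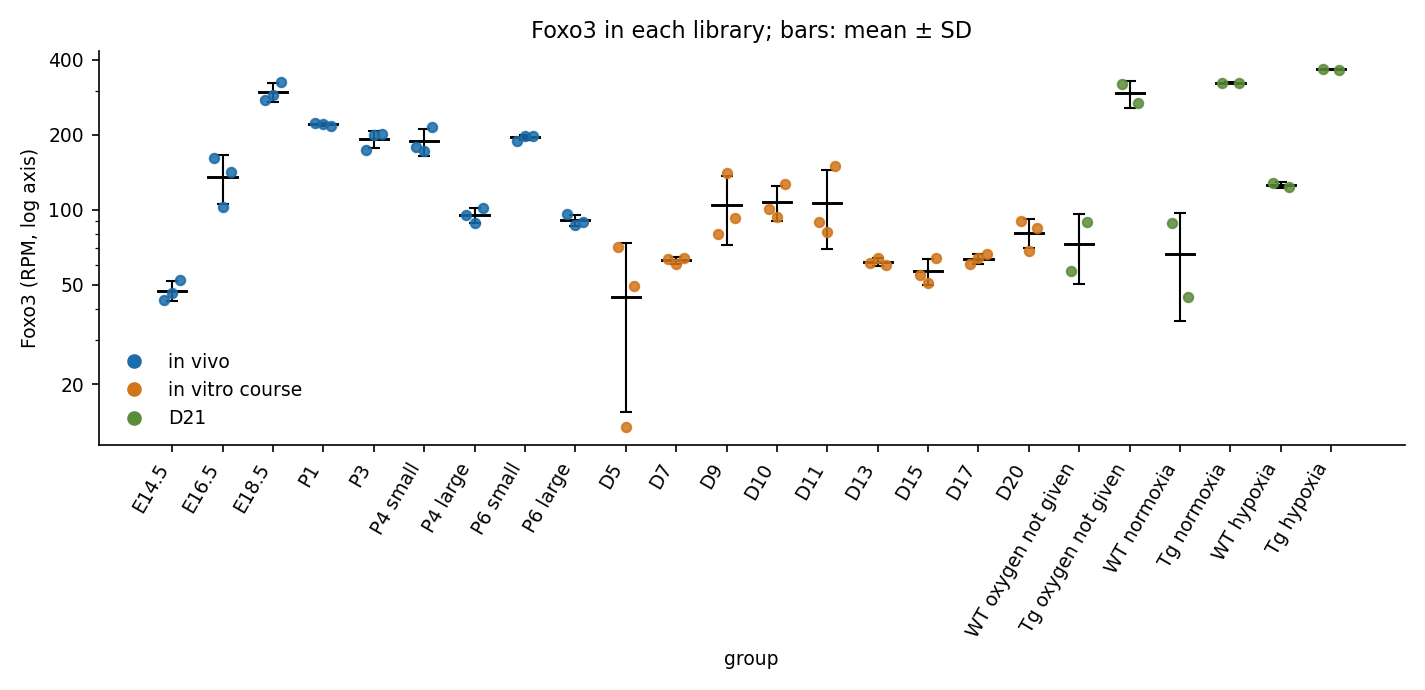
Foxo3 in RPM on a log axis for all 24 groups along the horizontal axis, each dot a library and bars the mean ± SD. WT hypoxia (126 RPM) lies above WT normoxia (66.6 RPM) at D21, and the 6 Tg libraries lie between 267 and 367 RPM.

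WT oocytes grown in 5% O2 were compared with WT oocytes in normoxia to show what low oxygen does to their RNA. Ldha, a classic target of the hypoxia-inducible factor HIF, rose from 27.5 ± 3 to 199 ± 61.6 RPM (n = 2; log2 change 2.78, adjusted p = 0.0049). The glycolytic kinase Pgk1 rose from 159 ± 11.7 to 380 ± 47.4 RPM (1.25) and Pdk1, which holds pyruvate back from the mitochondria, from 49.2 to 130 RPM (1.41). Gdf9 fell from 4110 ± 288 to 2190 ± 240 RPM (-0.91, adjusted p = 0.018) and Zp3 from 10200 ± 3220 to 4870 ± 312 RPM (-1.03, adjusted p = 0.029), while Kit rose from 522 ± 149 to 1070 ± 40.1 RPM (1.07, adjusted p = 0.011). Foxo3 rose by 0.99 with adjusted p = 0.035, and both hypoxia libraries lay above both normoxia libraries (44.8 and 88.5 RPM).

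Of 14392 genes 3237 were called, 2295 up and 942 down, 1419 of them at a log2 change of at least 1. After rescaling 1598 were up and 1460 down, with edgeR 1793 and 1866, and with DESeq2 2197 and 2522. The count ran widely when single libraries were left out, and only a few genes were called with the compared groups fitted alone (both given below). Foxo3 lost its call without WT normoxia replicate 2 (0.50, adjusted p = 0.18), without WT hypoxia replicate 1 (0.96, adjusted p = 0.18) and without WT hypoxia replicate 2 (adjusted p = 0.13). Its change was 0.74 both in edgeR (adjusted p = 0.037) and in DESeq2 (adjusted p = 0.015). Adam19 (2.31), the insulin receptor relative Insrr (2.25), Igfbp3 (2.18) and the glutamine carrier Slc38a1 (2.09) were with Ldha among the largest rises. Lect1 (-4.07), the chemokine Cxcl10 (-3.96), Gstm2 (-3.92), Clu (-3.76), Cpe (-3.69) and Ier3 (-3.50) fell most.

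Among 42 HIF targets 15 rose and 1 fell in WT hypoxia, or 18 and 1 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.012, or 0.63 with an estimated correlation). Vegfa was 4.7 against 7.51 RPM (adjusted p = 0.41), Slc2a1 had a log2 change of 0.52 (adjusted p = 0.065) and Bnip3 one of 0.31 (adjusted p = 0.27). Glycolysis genes had 10 up and 1 down of 19, or 11 and 1 adjusted over the list alone, such as Hk1 (1.47) and Pfkl (1.41), with a median of 0.77 (adjusted p = 0.0015, or 0.56 with an estimated correlation). The PI3K/FOXO pathway had 10 up and 1 down of 24, or 16 and 1 adjusted over the list alone, with Tsc2 (1.27) and Pdpk1 (1.17) up and a median of 0.74 (adjusted p = 0.00092, or 0.63 with an estimated correlation). FOXO targets split into 5 up and 7 down, with Ccnd2 (-2.41), Pdk4 (-2.39) and Klf6 (-2.10) down (median 0.34, test sign down, adjusted p = 0.72). Oocyte growth genes had 0 up and 20 down of 36, or 27 down adjusted over the list alone, such as Oosp1 (-1.70) and Omt2a (-1.68), with a median of -0.86 (adjusted p = 6.9e-16, or 0.45 with an estimated correlation). Meiotic prophase genes had 11 up of 35, or 12 adjusted over the list alone, such as Taf7l (1.86), Tex15 (1.69) and Stag3 (1.62), with a median of 0.50 (adjusted p = 0.0061, or 0.45 with an estimated correlation). Respiratory chain genes had 1 up and 1 down, or 0 adjusted over the list alone (-0.43, adjusted p = 2.5e-05) and ribosome genes 0 called (-0.33, adjusted p = 1e-05), each at 0.68 with an estimated correlation.

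Granulosa markers moved with low oxygen. Of 20 measured in the WT comparison 9 fell, or 11 fell and 1 rose adjusted over the list alone, with Amhr2 (-3.47) going from 33.4 ± 19 to 1.87 RPM, Inha (-3.33) from 84.4 ± 43.2 to 7 RPM (n = 2) and Wt1 (-3.16), and a list median of -1.17 (adjusted p = 2.9e-07, or 0.56 with an estimated correlation). Counts for stroma/theca markers were 1 up and 1 down of 14, or 0 and 1 adjusted over the list alone (-0.23, adjusted p = 0.04, or 0.63 with an estimated correlation). Endothelial markers had 3 up of 10, or 6 adjusted over the list alone, such as Cdh5 (2.35), with a median of 0.94 (adjusted p = 0.04), and blood/immune markers 0 of 9 (-0.80, adjusted p = 0.021), each at 0.63 with an estimated correlation.

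The same contrast in Tg oocytes asked how low oxygen acts where Foxo3 RNA is already high. Ldha rose from 31.1 ± 10.1 to 164 ± 70.6 RPM (n = 2; log2 change 2.33, adjusted p = 0.025), with Pgk1 (0.93, adjusted p = 0.034) and Eno1 (0.83, adjusted p = 0.035). Gdf9 was 1800 ± 425 against 3410 ± 441 RPM (-0.94, adjusted p = 0.067), and Foxo3 had a log2 change of 0.18 (adjusted p = 0.82). Granulosa genes fell, such as Amhr2 (-3.06), Wt1 (-2.92) and Inha (-2.72), and Xist fell from 130 ± 47.6 to 11.6 RPM (-3.40).

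In Tg 147 genes were called, 22 up and 125 down, 133 of them at a log2 change of at least 1, while 2018 had an unadjusted p under the threshold. edgeR called 365, 56 up and 309 down, and DESeq2 1044. The calls depended on each compared library. Fitted alone, Tg gave far more calls than WT, as given below. Insrr (1.4), Nuak1 (1.14) and Atp4a (0.97) were with Ldha among the largest rises, and Tgfb1i1 (-3.31), Axl (-3.08), Synpo (-3.05) and Cxcl10 (-3.02) fell most with Xist and Amhr2. None of the oocyte growth genes was called, or 28 were down adjusted over the list alone (median -0.76, adjusted p = 1.6e-20), and glycolysis genes had 3 up, or 10 adjusted over the list alone (0.46, adjusted p = 1.5e-05), each at 0.26 with an estimated correlation. HIF targets had 3 up, or 8 up and 1 down adjusted over the list alone (0.28, adjusted p = 0.0033, or 0.56 with an estimated correlation). Meiotic prophase had 2 up, or 7 adjusted over the list alone, such as Taf7l (1.64) and Syce1 (0.75), with a median of 0.42 (adjusted p = 1.5e-05, or 0.16 with an estimated correlation). FOXO targets had 0 up and 1 down, Ccnd2 (-2.71), or 5 down adjusted over the list alone (0.09, test sign down, adjusted p = 0.34). The p53 targets had 0 called, or 1 adjusted over the list alone (0.20, adjusted p = 0.048) and transposon defence 0, or 5 adjusted over the list alone (0.15, adjusted p = 0.048), each at 0.56 with an estimated correlation. Respiratory chain (0.30, adjusted p = 0.00089) and ribosome genes (0.37, adjusted p = 1.3e-05), each at 0.75 with an estimated correlation, had medians of the other sign than in WT. With the other-cell score, which cannot be separated from oxygen, they were -0.76 and -0.68. The WT medians were 0.05 (adjusted p = 0.54) and 0.01 (adjusted p = 0.32) with the length trend removed, and both lists lay 1.09 and 1.04 higher in WT normoxia replicate 2 than in replicate 1. Granulosa markers had 4 down, or 14 adjusted over the list alone (-1.27, adjusted p = 5.3e-11, or 0.29 with an estimated correlation). Stroma/theca markers had 0, or 1 down adjusted over the list alone (-0.46, adjusted p = 0.003, or 0.56 with an estimated correlation). Endothelial markers had 0 called (0.62, adjusted p = 0.045, or 0.68 with an estimated correlation). Blood/immune markers had 0 called (0.19, adjusted p = 0.93).

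Between the WT and Tg comparisons, which share no libraries, 22 genes were up in both where 3.51 were expected, 122 were down in both where 8.18 were expected and 0 were opposite. Pearson's r was 0.73 and Spearman's rho 0.62 across genes (not independent replicates). The interaction of oxygen and genotype called 0 genes by limma, with 869 unadjusted, 0 by edgeR and 2 by DESeq2, but without WT normoxia replicate 1 it called 2338. Foxo3 had an interaction of -0.81 (adjusted p = 0.65). The interaction passed for respiratory chain (median 0.71, adjusted p = 6.7e-19), ribosome (0.72, adjusted p = 1.2e-23), blood/immune (0.96, adjusted p = 0.0023) and PI3K/FOXO genes (-0.53, adjusted p = 0.00056), each at 0.8 with an estimated correlation, and for oocyte growth (0.14, adjusted p = 0.01) and DNA methylation genes (-0.46, adjusted p = 0.016), each at 0.92 with an estimated correlation. With the length trend removed, respiratory chain was 0.23, ribosome 0.34 and oocyte growth -0.18, the other sign. FOXO targets (-0.16, adjusted p = 0.86), HIF targets (-0.26, adjusted p = 0.33), granulosa markers (0.14, adjusted p = 0.45), stroma/theca markers (-0.09, test sign up, adjusted p = 0.81) and endothelial markers (-0.43, adjusted p = 0.46) did not pass.

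Over both genotypes, 4 hypoxia libraries were compared with 4 normoxia libraries. Ldha rose from 29.3 ± 6.41 to 181 ± 57.7 RPM (n = 4; log2 change 2.55, adjusted p = 0.0007), and Pgk1 (1.09), Pdk1 (1.10), Hk1 (1.27) and Slc2a1 (0.43, adjusted p = 0.037) rose with it. Gdf9 fell from 3760 ± 506 to 1990 ± 364 RPM (-0.93, adjusted p = 0.0035), Zp3 by 0.86 (adjusted p = 0.015) and Zp2 by 0.54 (adjusted p = 0.037). Kit (0.72, adjusted p = 0.0074), Sycp3 (0.75) and Sohlh1 (0.62), all more abundant in small oocytes of P6, rose. With the other-cell score as a covariate Sohlh1 (-0.18) and Sycp3 (-0.07) had the other sign and Kit did not pass (1.24, adjusted p = 0.058), and Sohlh1 was -0.02 with the granulosa score. Foxo3 had a log2 change of 0.58 (adjusted p = 0.058).

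In this pooled comparison 3648 genes were called, 2332 up and 1316 down, 717 at a log2 change of at least 1, and the split was 1639 and 1849 after rescaling. edgeR called 4015, DESeq2 4848, and the fit with the other-cell score as a covariate 0. Left out one at a time, the libraries gave 5767 (WT normoxia replicate 1), 3403 (WT normoxia replicate 2), 2140 and 1068 (Tg normoxia replicates 1 and 2), 1071 and 1685 (WT hypoxia replicates 1 and 2) and 1817 and 966 (Tg hypoxia replicates 1 and 2). Igfbp3 (1.87), Insrr (1.83), Adam19 (1.80), Slc38a1 (1.60) and the retinoid binder Crabp1 (1.52) rose most with Ldha, and Cxcl10 (-3.49), Lect1, Gstm2 (-3.36), Tgfb1i1, Clu and Amhr2 (-3.26) fell most. Oocyte growth genes had 29 down, or 34 adjusted over the list alone (median -0.84, adjusted p = 1.9e-19, or 0.31 with an estimated correlation). HIF targets had 17 up and 2 down, or 19 and 2 adjusted over the list alone (0.42, adjusted p = 0.0096, or 0.68 with an estimated correlation). Glycolysis had 11 up and 1 down (0.60, adjusted p = 0.00067, or 0.4 with an estimated correlation). Meiotic prophase had 13 up and 0 down, or 14 adjusted over the list alone (0.47, adjusted p = 0.00078, or 0.31 with an estimated correlation). The PI3K/FOXO pathway had 8 up and 1 down, or 14 and 1 adjusted over the list alone (0.42, adjusted p = 0.0064, or 0.68 with an estimated correlation). FOXO targets had 4 up and 7 down, or 6 and 7 adjusted over the list alone (0.21, test sign down, adjusted p = 0.68). Granulosa markers had 1 up and 14 down, or 1 and 15 adjusted over the list alone (-1.23, adjusted p = 4.2e-09, or 0.4 with an estimated correlation). Counts for stroma/theca markers were 3 down (-0.53, adjusted p = 0.0096) and endothelial markers 6 up (0.79, adjusted p = 0.039), each at 0.68 with an estimated correlation. Counts for blood/immune markers were 0 called (-0.35, adjusted p = 0.15).

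The granulosa score, the mean log2(RPM + 1) of the granulosa markers, was 1.36 to 1.57 in the 4 hypoxia libraries and 2.17 to 3.80 in the other 8 libraries of D21. It was 1.16 in P6 large oocytes and 1.41 at D20. As the score fell, the HIF, glycolysis and meiotic lists rose and the oocyte growth list fell in both genotypes. None of these list calls held with an estimated correlation. The PI3K/FOXO list passed with it in WT but had a median of 0.23 in Tg (0 called, adjusted p = 0.19).

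**Figure D4:**
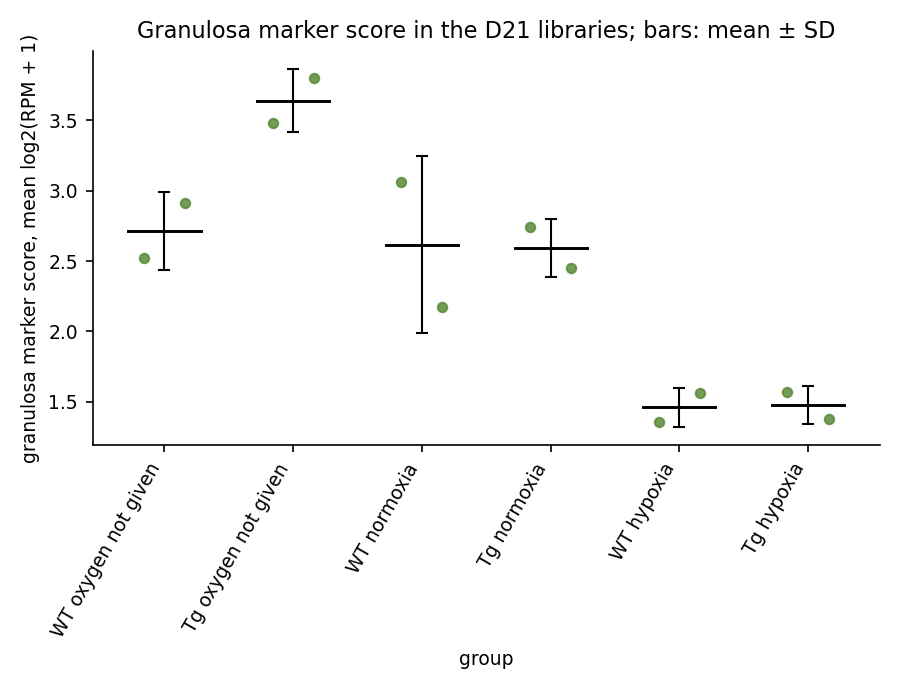
Granulosa score, in mean log2(RPM + 1) of the marker list, for the groups along the horizontal axis, with each dot a library. The 4 hypoxia libraries lie below the other D21 libraries.

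Genes that part small from large oocytes in the ovary were followed at D21 to show whether low oxygen or the transgene moves cultured oocytes toward the small state. In WT hypoxia the small-oocyte list, with 3029 of 3054 genes measured, had a median log2 change of 0.49, with 1051 genes up, 106 down and 79.6% of its genes above 0 (adjusted p = 1.6e-12), and the large-oocyte list, with 1456 of 1484 measured, had a median of -0.45, with 0 up and 330 down (adjusted p = 5.9e-26), each at 0.13 with an estimated correlation. In Tg hypoxia the medians were 0.33 (adjusted p = 1.5e-21, or 0.1 with an estimated correlation) and -0.49 (adjusted p = 5e-48, or 0.1 with an estimated correlation), with 20 up and 30 down in the small-oocyte list and 13 down in the large-oocyte list. Tg against WT gave 0.32 (adjusted p = 3.6e-07, or 0.22 with an estimated correlation) and -0.14 (adjusted p = 4.1e-13, or 0.24 with an estimated correlation) in normoxia, where the latter was 0.03 without WT normoxia replicate 1. In hypoxia it gave 0.14 (adjusted p = 2.7e-21, or 0.1 with an estimated correlation) and -0.19 (adjusted p = 1.6e-49, or 0.1 with an estimated correlation), and 0 list members were called in either oxygen condition. With the oxygen not given the medians were 0.52 with 481 up and 1 down (adjusted p = 1.9e-17, or 0.1 with an estimated correlation) and -0.27 with 3 up and 66 down (adjusted p = 6.4e-34, or 0.12 with an estimated correlation).

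The difference of the mean scores of both lists, small minus large, was 2.04 ± 0.09 (SD, n = 3) in P6 small and -2.56 ± 0.03 in P6 large oocytes. In culture it was 1.73 ± 0.24 at D11, -0.73 ± 0.2 at D13 and -2.67 ± 0.06 at D20. At D21 it was -0.65 ± 0.08 in WT normoxia, -0.18 ± 0.34 in Tg normoxia, 0.22 ± 0.21 in WT hypoxia and 0.58 ± 0.19 in Tg hypoxia (n = 2 each). The WT hypoxia and P6 comparisons shared 2085 genes up (1260 expected) and 491 down (214 expected), with 224 opposite. Pearson's r was 0.44 and Spearman's rho 0.45 across 13955 genes, not independent replicates. Tg hypoxia and P6 shared 21 up (11.6 expected) and 20 down (28.8 expected), with 49 opposite, at r = 0.52 and rho = 0.68.

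**Figure D5:**
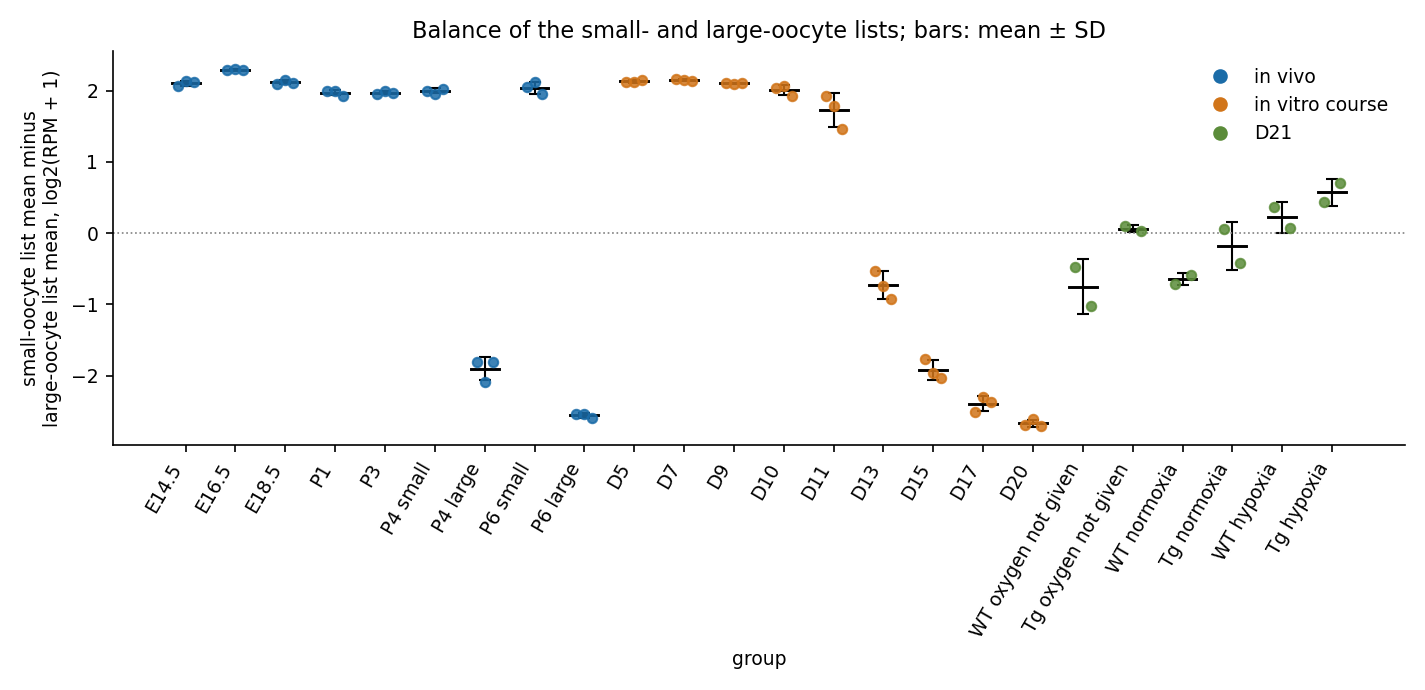
Small-oocyte score minus large-oocyte score, in mean log2(RPM + 1), for the groups along the horizontal axis, with each dot a library. The D21 groups lie between P6 small (2.04) and P6 large oocytes (-2.56), from -0.65 in WT normoxia to 0.58 in Tg hypoxia among those of given oxygen.

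Tg oocytes were compared with WT oocytes to show what the transgene changes. Scx, a transcription factor of tendon precursors at chromosome 15 from 76457452 to 76459458 on the plus strand (ENSMUSG00000034161.8), was called in every Tg against WT comparison, but not in normoxia or with the oxygen not given when only the compared groups were fitted. It was 41.8 ± 4.85 against 2.5 ± 0.25 RPM in normoxia (n = 2; log2 change 3.61, adjusted p = 3e-04) and 34.2 ± 3.61 against 1.54 ± 0.0153 RPM in hypoxia (3.79, adjusted p = 0.00019). Foxo3 had a log2 change of 2.34 in normoxia (adjusted p = 0.062) and 1.53 in hypoxia (adjusted p = 1), although Tg and WT libraries did not overlap. Over both oxygen conditions Foxo3 was 344 ± 24.7 against 96.2 ± 38.6 RPM (n = 4; 1.94, adjusted p = 0.015, with 0.0035 in edgeR) and Scx 38 ± 5.61 against 2.02 ± 0.573 RPM (3.70, adjusted p = 7.6e-06).

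In normoxia limma called 1 gene, Scx, with 3454 unadjusted, edgeR 2 and DESeq2 1607. Without WT normoxia replicate 1 the count was 5202. In hypoxia limma called 1, again Scx, with 68 unadjusted, edgeR 1 and DESeq2 2. Over both oxygen conditions limma called 2, with 2121 unadjusted, edgeR 2 and DESeq2 237. That count was 3183 without WT normoxia replicate 1, 2 without WT normoxia replicate 2 and 1 without any of the other 6 libraries, where Foxo3 lost its call with adjusted p between 0.13 and 0.15. The oocyte growth list had 0 called, or 12 down adjusted over the list alone, with a median of -0.39 over both conditions (adjusted p = 9.2e-20, or 0.6 with an estimated correlation), -0.46 in normoxia (adjusted p = 1.5e-11, or 0.88 with an estimated correlation) and -0.33 in hypoxia (adjusted p = 3.6e-26, or 0.34 with an estimated correlation). The PI3K/FOXO pathway had 1 called, Foxo3, with a median of 0.33 over both conditions (adjusted p = 0.00076, or 0.74 with an estimated correlation). FOXO targets had 0 called, or 2 up adjusted over the list alone (0.20, adjusted p = 0.15), and passed in hypoxia alone with a median of 0.12 (adjusted p = 0.013, or 0.68 with an estimated correlation). HIF targets had 0 called (0.02, test sign down, adjusted p = 0.4). In normoxia alone, with 0 members called, the test passed for respiratory chain genes (-0.63, adjusted p = 6.6e-17), ribosome genes (-0.53, adjusted p = 8.5e-17), the PI3K/FOXO pathway (0.63, adjusted p = 0.00031, with 11 up adjusted over the list alone) and blood/immune markers (-0.91, adjusted p = 0.00048), each at 0.88 with an estimated correlation. The change correlated at 0.57 with transcript length across genes (not independent replicates), and with that trend removed the respiratory chain and ribosome medians were -0.12 and -0.15. From WT normoxia replicate 1 to 2 respiratory chain moved by 1.09, ribosome by 1.04, blood/immune by 2.14 and PI3K/FOXO by -0.59. Over both conditions the medians of respiratory chain and ribosome genes were -0.27 (adjusted p = 5.3e-12, or 0.74 with an estimated correlation) and -0.17 (adjusted p = 4e-08, or 0.91 with an estimated correlation), and -0.04 and 0.01 with the length trend removed.

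In hypoxia alone, with 0 members called, ribosome genes (0.18, adjusted p = 2e-05, or 0.87 with an estimated correlation) and endothelial markers (-0.50, adjusted p = 1.3e-06, or 0.52 with an estimated correlation) passed. Small medians also passed there for HIF targets (-0.04, adjusted p = 0.0026), glycolysis (-0.06, adjusted p = 0.041), proliferation (-0.06, adjusted p = 0.011), DNA methylation (-0.15, adjusted p = 0.029), autophagy (0.08, adjusted p = 0.029) and meiotic prophase (0.13, adjusted p = 0.041), each at 0.68 with an estimated correlation. Markers of other cells over both conditions had 0 called, with a median of -0.04 for granulosa (adjusted p = 0.33), -0.26 for endothelium (adjusted p = 0.025, or 0.74 with an estimated correlation), -0.42 for blood and immune cells (adjusted p = 0.001, or 0.74 with an estimated correlation) and an adjusted p of 0.94 for stroma and theca.

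Among the libraries of no given oxygen, Tg again exceeded WT in Scx, at 44.1 ± 4.3 against 2.91 ± 1.19 RPM (n = 2; log2 change 3.56, adjusted p = 0.00034), and in Foxo3 (2.02, adjusted p = 0.027). Vcam1 (2.85), Myof (2.59), Fbn1 (2.56), Icam1 (2.43) and Elmsan1 (2.42) were higher, and Sdcbp2 (-1.37), Htra4, Grm2, Fbxw26, Rfpl4 (-1.11) and Zcchc10 lower. The FOXO targets Klf6 (1.83), Klf2 (1.62) and Fbxo32 (1.57) were higher in Tg, and so were the p53 targets Fas (2.01) and Btg2 (1.55). With the other-cell score as a covariate none of these FOXO targets passed, and Klf6 (-0.09) and Klf2 (-0.50) had the other sign. Gdf9 had a log2 change of -0.63 (adjusted p = 0.085). The granulosa score was 3.64 ± 0.23 in Tg and 2.71 ± 0.28 in WT of this set.

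Here 986 genes were called, 899 up and 87 down, 671 at a log2 change of at least 1, and rescaling gave 669 and 209, while edgeR called 1 and DESeq2 1573. The count was 2 without WT replicate 1, 3171 without WT replicate 2, 3 without Tg replicate 1 and 2 without Tg replicate 2, and Foxo3 lost its call in 3 of the 4 cases (adjusted p between 0.06 and 0.14). FOXO targets had 8 up, or 19 adjusted over the list alone (median 0.89, adjusted p = 8.1e-05) and the p53 targets 6 up, or 8 adjusted over the list alone (0.52, adjusted p = 0.0075), each at 0.83 with an estimated correlation. Of the oocyte growth genes 3 were down, or 25 adjusted over the list alone (-0.66, adjusted p = 5.5e-22, or 0.48 with an estimated correlation). The PI3K/FOXO pathway had 1 up (0.34, adjusted p = 0.035, or 0.83 with an estimated correlation). Respiratory chain genes had a median of -0.28 (adjusted p = 1.5e-08), ribosome genes -0.02 (adjusted p = 0.0075) and proliferation genes -0.07 (adjusted p = 0.016), each at 0.83 with an estimated correlation. With the length trend removed the ribosome median was 0.20, and with the other-cell score the respiratory chain (1.04), ribosome (1.33) and PI3K/FOXO medians (-0.19) had the other sign. HIF targets had 4 up, or 8 up and 1 down adjusted over the list alone (0.30, adjusted p = 0.43). Granulosa markers had 1 up, or 12 adjusted over the list alone (1.12, adjusted p = 0.0034, or 0.83 with an estimated correlation). Stroma/theca markers had 1 up, or 3 adjusted over the list alone (0.84, adjusted p = 0.19). Endothelial markers had 0 called (0.25, test sign down, adjusted p = 0.55). Blood/immune markers had 0 called (adjusted p = 0.28).

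Tg hypoxia was set against WT normoxia as the pair in which oxygen and transgene both differ. It gave 4336 calls, 3059 up and 1277 down, 1997 at a log2 change of at least 1, with a rescaled split of 2023 and 2027, and edgeR called 4560 and DESeq2 5463. Without single libraries the count was 6376 (WT normoxia replicate 1), 2548 (WT normoxia replicate 2), 1508 (Tg hypoxia replicate 1) and 23 (Tg hypoxia replicate 2). Scx (3.33), Sobp (2.69), Vwf (2.59), Insrr (2.57) and Foxo3 (2.52, adjusted p = 0.0026) were among the largest rises, and Cxcl10 (-3.82), Lect1 (-3.48), Tgfb1i1, Gstm2, Lgals3 and Clu fell most. Oocyte growth genes had 30 down, or 36 adjusted over the list alone (median -1.14, adjusted p = 5.5e-21, or 0.35 with an estimated correlation). The PI3K/FOXO pathway had 11 up and 1 down, or 17 and 1 adjusted over the list alone (0.72, adjusted p = 0.0017, or 0.78 with an estimated correlation). Meiotic prophase had 14 up and 1 down, or 16 and 2 adjusted over the list alone (0.71, adjusted p = 0.0047, or 0.35 with an estimated correlation). Glycolysis had 10 up and 1 down (0.61, adjusted p = 0.017, or 0.78 with an estimated correlation). HIF targets had 14 up and 2 down, or 16 and 2 adjusted over the list alone (0.41, adjusted p = 0.14). FOXO targets had 6 up and 6 down, or 7 and 6 adjusted over the list alone (0.41, adjusted p = 0.94). Granulosa markers had 10 down, or 12 adjusted over the list alone (-1.25, adjusted p = 4.1e-07, or 0.77 with an estimated correlation). Counts for blood/immune markers were 1 down, or 0 adjusted over the list alone (-0.75, adjusted p = 0.019, or 0.78 with an estimated correlation). Of the respiratory chain genes 3 were up and 1 down, or 0 adjusted over the list alone (-0.33, adjusted p = 0.00063), and ribosome genes had 0 called (-0.15, adjusted p = 0.0088), each at 0.81 with an estimated correlation, with medians of 0.08 and 0.20 when the length trend was removed. Among stroma/theca markers 1 was up and 1 down (-0.36, adjusted p = 0.079), and 1 endothelial marker was up, or 0 adjusted over the list alone (0.53, adjusted p = 0.49).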

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

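The splits of samples into other groups were planned, while the tests of the 3 patterns weighed here were chosen only after the result was seen.

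The change between small and large oocytes differed between P6 and P4 in 1312 genes (906 above and 406 below 0, 338 by at least 1 on the log2 scale, 3703 unadjusted). Of these, 1211 had the same sign at both ages and 1243 (94.7%) were larger at P6. The difference had a median of 0.46 for ribosome genes (29 called, adjusted p = 2.1e-17, or 0.43 with an estimated correlation), 0.35 for respiratory chain genes (8 called, adjusted p = 1.7e-07, or 0.53 with an estimated correlation) and -0.48 for oocyte growth genes (5 called, adjusted p = 1.6e-06, or 0.38 with an estimated correlation).

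Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05, and in each the real split, 1 of the 10, called the most genes. The highest other split called 0 genes at P6, P4, D20 against D11 and D20 against P6 small, 2 for D20 against P6 large, 5 for P3 against E18.5, 11 for E18.5 against E14.5 and 2186 for D11 against D5. The last number points to a structure within the D5 and D11 libraries. For hypoxia with genotypes merged, the real split of its 8 libraries called 2293 genes and the highest other 1. Hence 1 of 35 splits (2.86%) reached the real count. For Tg over both oxygen conditions the real split called 1, and 2 of 35 (5.71%) reached that, the other being the split by oxygen with 2293.

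Of 13 granulosa markers with at least 5 RPM in normoxia, 7 were below 1 RPM in P6 large oocytes (Foxl2, Amh, Fst, Inha, Amhr2, Wt1, Nr5a1). All 7 fell 6.99-fold to 13.3-fold in hypoxia (median 9.01). Picked as high in normoxia, they cannot test less follicle-cell RNA. Of 24 granulosa genes P6 small oocytes hold 11 and P6 large oocytes 9 at 1 RPM or more. Less follicle-cell RNA would raise the share of oocyte genes, which the median of -0.84 of the oocyte growth list argues against as its cause. Scaling and transcript length are argued against by 3488 calls after rescaling and 3660 without the length trend. Whether follicle cells were fewer on the oocytes or carried less of these RNAs stays open.

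WT normoxia replicate 2 lay apart from replicate 1, with a chi-square per gene of 102 between them, where the other D21 pairs had 5.56 to 29.7. Ldha at 25.4 RPM (lowest hypoxia library 114 RPM) argues against a swapped hypoxia label. A large-list minus small-list change of -0.13 (P6 large against small 4.03) argues against more advanced oocytes. An earlier stage was not tested. Transcript length may be part of the cause, with a Spearman correlation of -0.49 between length and the change from replicate 1 across genes, which are not independent replicates. As the whole cause it is argued against by 3985 calls after removal of the length trend, by a respiratory chain median of 0.36 (1.09 before) and by a ribosome median of 0.51 (1.04 before). RNA of other cells also differed, with medians from replicate 1 to 2 of -1.13 for granulosa, -0.9 for stroma and theca and 2.14 for blood and immune markers, against -0.27 for all genes, and its part was not tested.

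Scx was 31.6 to 47.1 RPM in the 6 Tg libraries and 1.53 to 3.75 RPM in the 6 WT libraries. Stray reads of Bop1, which overlaps Scx on the other strand, are argued against by a Bop1 change of -0.07 (SE 0.09). A change across the region is argued against by a median of 40 genes within 500 kb only 0.02 above that of all genes, with 0 called. A growth stage is argued against by a highest value of 14.4 RPM in any library without the transgene. An effect of Foxo3 on Scx and a feature of the Tg cell line could both explain it and stay open, because no second line was measured here.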

How the results depend on the processing

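For the values given here the cause was not tested, unless stated. The settings with a length trend, an other-cell or granulosa score or thinned reads were added after the main results were seen. Every in vivo count, and that of D20 against P6 small oocytes, stayed within 1.5 times its value under all settings.

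With only the compared groups in the fit, which lowers the degrees of freedom, the counts were 2625 for D11 against D5, 3816 for D20 against P6 large, 10 for WT hypoxia, 3854 for Tg hypoxia and 0 for Tg hypoxia against WT normoxia (4653 unadjusted). Those of Tg against WT were 0 in normoxia (1560 unadjusted), 4 in hypoxia, 1 over both conditions and 0 with the oxygen not given (2771 unadjusted). DESeq2 called 1044 genes for Tg hypoxia and 1607, 2, 237 and 1573 for Tg against WT in the same order, and 2 for the interaction. edgeR called 365 for Tg hypoxia, 2 for Tg against WT in normoxia and 1 with the oxygen not given. Rescaling and the length correction each gave 2 for Tg against WT in normoxia. Without a filter the counts were 0 for Tg hypoxia, 1 for Tg over both conditions and 479 with the oxygen not given, where a pseudocount of 0.25 gave 557. Same-numbered replicates correlated at -0.17 to 0.15, so their pairing is not established. As blocks they gave 94 for Tg hypoxia and 1 each for Tg over both conditions and with the oxygen not given.

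With the other-cell score as a covariate the counts were 2559 for D11 against D5, 6268 for D20 against D11, 0 for Tg hypoxia, 0 for hypoxia over both genotypes (4947 unadjusted), 3551 for Tg against WT in normoxia and 0 with the oxygen not given (1303 unadjusted). The granulosa score gave 6067 for WT hypoxia, 0 for Tg hypoxia and 3472, 2, 906 and 1 for Tg against WT in normoxia, in hypoxia, over both and with the oxygen not given. Thinned reads, which bear on depth, gave 2081, 57 and 2229 for hypoxia in WT, in Tg and over both, 2 and 1 for Tg against WT in normoxia and with the oxygen not given, and 2811 for Tg hypoxia against WT normoxia.

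Leaving out 1 library leaves an arm of D21 with a lone sample, assumed to vary like the other groups. Counts then ran from 1422 to 2063 for D20 against P6 large, 16 to 6011 for WT hypoxia, 0 to 0 for Tg hypoxia, 966 to 5767 over both genotypes, 1 to 5202 for Tg against WT in normoxia, 1 to 3183 over both conditions, 2 to 3171 with the oxygen not given, 0 to 2338 for the interaction and 23 to 6376 for Tg hypoxia against WT normoxia. The small-oocyte and large-oocyte lists stayed past the threshold, but medians of Tg against WT moved. The large-oocyte median ran from -0.3 to 0.03 in normoxia, -0.29 to -0.09 in hypoxia and -0.56 to -0.02 with the oxygen not given, and the small-oocyte median from 0.21 to 0.46 in normoxia and 0.08 to 0.2 in hypoxia. The large-oocyte median in WT hypoxia ran from -0.6 to -0.3. With an estimated correlation none of these calls held, at 0.49 and -0.45 in WT hypoxia, 0.33 and -0.49 in Tg hypoxia, 0.32 and -0.14 for Tg in normoxia, 0.14 and -0.19 for Tg in hypoxia, and 0.52 and -0.27 with the oxygen not given.

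Some signs reversed. Rescaling took Figla to -0.01 at P4. The length correction took Sdhd to 0.01 in WT hypoxia, the ribosome list to 0.2 with the oxygen not given and to 0.2 in Tg hypoxia against WT normoxia, and the oocyte growth list to -0.18 in the interaction. The granulosa score took Sohlh1 to -0.02 in hypoxia over both genotypes. All others came with the other-cell score, for Klf4 (-0.2, D11 against D5) and Dppa3 (-0.14, D20 against D11). In Tg hypoxia they were the respiratory chain (-0.76) and ribosome lists (-0.68), and over both genotypes Crabp1 (-0.14), Sohlh1 (-0.18) and Sycp3 (-0.07). With the oxygen not given they were Fbn1 (-0.32), Klf6 (-0.09), Klf2 (-0.5) and the PI3K/FOXO (-0.19), respiratory chain (1.04) and ribosome lists (1.33). In Tg hypoxia against WT normoxia they were Sohlh1 (-0.24), Sycp3 (-0.06) and Klf2 (0.4).

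Of the gene calls, the other-cell score kept 203, lost 111 and reversed 11, the granulosa score kept 89 and lost 60, and thinned reads kept 132 and lost 47. Leaving out a library kept 3266 and lost 430, edgeR kept 592 and lost 53, and rescaling kept 621 and lost 23. Of the list calls, the other-cell score kept 59, lost 19 and reversed 5, the length correction kept 119, lost 12 and reversed 3, and rescaling lost 11.

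By the 2000 most variable genes, 12 of the 15 closest in vivo groups stayed. WT hypoxia (0.847) and Tg of no given oxygen (0.762) were then closest to P4 large and D10 to E14.5 (0.754), while Pearson's r kept all 15.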

Other observations

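The meiotic switch Stra8 fell in vivo from 582 ± 71.7 RPM at E14.5 to 21.4 ± 33.3 RPM at E16.5 (n = 3), and in culture from 775 ± 158 RPM at D5 to 262 ± 190 RPM at D11 and 0.231 RPM at D13. Gdf9 rose between those last days from 124 ± 119 to 2290 ± 452 RPM, and Figla stood at 335 ± 14.3 RPM at D13. Pou5f1, a pluripotency factor, went in vivo from 143 ± 18.8 RPM at E14.5 to 9.99 ± 3.07 RPM at E16.5 and back to 203 RPM at P3.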
